A study of Mus musculus with 6 samples.

How the data were processed

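Thymus of adult female (AKR/J x FVB/NJ)F1 and (DBA/2J x FVB/NJ)F1 mice was snap-frozen, RNA was extracted with Trizol, and biotin-labelled target was made by the standard Affymetrix procedure, per the labels' protocols. The 6 arrays, 3 per cross, were placed in their groups from the sample titles and source names, and all 6 entered the comparison. The deposited table held 45101 probe sets per array as log2 values, made by the authors. MAS5 and RMA are named per the submitters' processing notes, without a role or a version. Which of them made the deposited log2 values is not given in the sources used here. The values ran from 2.47 to 14.4 and the sorted arrays differed by a mean SD of 0.0291, the form of quantile-normalized RMA values. Such a summary compresses differences of dim probe sets and forces the arrays to nearly the same distribution. No detection calls, array dates or batches were used here. No pair of arrays held identical values.

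Array correlations over all 45101 probe sets, controls included, ran from 0.994 to 0.996 within a cross (6 pairs) and from 0.984 to 0.989 between crosses (9 pairs). The first principal component of the tested probe sets held 69.0% of the variance and separated the crosses.

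The deposited values were used without further normalization. The 64 control probe sets were left out of the tests, which left 45037. A probe set was tested if it lay above the 40th percentile of its array on at least 3 of 6 arrays, which kept 27385. Gene symbols came from the platform annotation, which gave 1 symbol for 34945 probe sets, several for 932 and none for 9160. Of 34958 probe sets with 1 symbol, controls included, 34754 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The table was used for names and for which genes neighbour each other, since the assembly behind the array annotation is not given in the sources used here. A gene was represented by its tested probe set with the highest mean over all 6 arrays among those with exactly 1 symbol, which gave 12855 genes. Of these, 5918 had several tested probe sets, and opposite calls among them are given beside the gene.

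Differences were tested with lmFit and eBayes (trend) in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probe sets or over all genes and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The 31 gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01, then with the correlation estimated per list, and with fry. Adjusted p-values over a list alone were computed from the same limma p-values. The fit was tested on simulated values for 27385 probe sets with 200 of them changed. At a log2 change of 0.5 it recovered 49 (24.5%) with 5 false among 54 calls, at a log2 change of 1 it recovered 177 (88.5%) with 10 false among 187 calls, and with no change it made 0 calls. In the data 27.2% of probe sets were called, a far larger share than was changed here. The recovered shares thus need not hold for the data.

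The limma fit, the list tests, the lists, the alternatives except 1 and the rule for named genes were fixed before the data were examined. Some tests of technical explanations were chosen later, as said where they are given. By that rule the text names the 12 called genes with the largest log2 difference in each direction whose groups did not overlap. From each list the rule takes up to 4 called members with the smallest adjusted p, or up to 2 members as values where none passed. The text gives only some of these list members, and none from the muscle, red cell, and parathyroid and thyroid lists. H2-Ea, Thy1, Gpnmb, Klrd1, Glo1, Fv1 and Xist were always given, and Soat1, also in the rule, was not among the genes tested. Genes outside the rule are given as named after their values were seen. The alternatives were 2 other filters on dim probe sets, 3 normalizations, a floor at the 20th percentile, 2 other variance models, array weights, the replicate number as a block, each array left out in turn, a t-test with equal variance per probe set, the mean of a gene's probe sets, and 2 other list tests. An alternative without the probe sets that can match several transcripts was chosen after seeing the data.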

Results

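Thymus RNA from adult female mice of 2 F1 crosses was measured on single-channel Affymetrix mouse arrays, with 3 arrays of (AKR/J x FVB/NJ)F1 thymus (the AKR cross) and 3 arrays of (DBA/2J x FVB/NJ)F1 thymus (the DBA cross). Both crosses share the FVB/NJ parent and differ in the other parent. AKR/J is an inbred strain known for spontaneous T cell lymphoma of the thymus. The design text asks how basal gene expression in the thymus differs between these genotypes. Each array gave 45101 probe set values on a log2 scale, with array medians from 5.92 to 5.94. The number of arrays limits the precision of each difference. Differences below are AKR cross minus DBA cross on the log2 scale, with the standard error (SE), so a negative value was lower in the AKR cross. A gene was called where limma with Benjamini-Hochberg adjustment gave an adjusted p under 0.05.

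The thymus of the 2 crosses differed in many genes, mostly by small amounts. Prss22, a serine protease gene, was the gene with the largest difference among those higher in the AKR cross, at 9.05 ± 0.13 against 5.24 ± 0.18 (mean ± SD, n = 3 each), which was 14.0-fold, with 2 of the 3 DBA arrays below the 40th percentile of their array, so the fold is not exact. Slc15a2, a peptide transporter gene, was 11.6-fold higher in the DBA cross, at 10.66 ± 0.59 against 7.12 ± 1.47 (mean ± SD, n = 3 each). The log2 difference of Slc15a2 went from -3.53 to -2.69 without AKR replicate 1, its 2 other probe sets were not called, and 2 of 19 settings lost the call. Zbtb16, which encodes the transcription factor PLZF of innate-like T cells, was 4.25-fold higher in the DBA cross. H2-Ea, the alpha chain gene of the class II molecule H2-E, was 3.77-fold higher in the DBA cross. Among the gene groups, proliferation genes and B cell markers were higher in the AKR cross, and interferon-stimulated genes, innate-like T cell markers and medullary epithelial markers were higher in the DBA cross by camera with a preset correlation, and no list passed with an estimated correlation (lowest adjusted p = 0.743, limma).

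Of 12855 genes tested with limma and Benjamini-Hochberg adjustment, 3084 were called, with 1604 higher in the AKR cross and 1480 higher in the DBA cross. After quantile normalization of the values, 62.0% of called genes were higher in the AKR cross, against 52.0% without it. With 1 array left out fewer called genes were higher in the AKR cross than in the DBA cross in 4 of 6 cases, with shares of 46.4% without AKR replicate 1, 45.4% without AKR replicate 3, 48.5% without DBA replicate 2 and 47.2% without DBA replicate 3. Differences of at least 2-fold were fewer and leaned to the DBA cross, with 28 genes higher in the AKR cross and 90 higher in the DBA cross. With the mean of a gene's probe sets these counts were 18 and 82, a move of over 1.5 times for the AKR cross. Among called genes, 82.4% differed by less than 1.5-fold. At the level of probe sets, 7449 of 27385 (27.2%) were called, with 3338 higher in the AKR cross and 4111 higher in the DBA cross. The groups did not overlap for 5643 genes (43.9%), where chance gives 10%. The count of called genes moved by over 1.5 times without AKR replicate 2 (1963 genes), without DBA replicate 2 (1843 genes) and without DBA replicate 3 (1950 genes). The count higher in the AKR cross (1604) moved by over 1.5 times without any of 5 arrays, to 987, 1015 and 999 without AKR replicates 1, 2 and 3, and to 893 and 920 without DBA replicates 2 and 3. The count higher in the DBA cross (1480) did so without AKR replicate 2 (948) and without DBA replicate 2 (950). Probe sets higher in the AKR cross did so without DBA replicate 2 (2211) and without DBA replicate 3 (2158). Without sharing of variance between genes, 1367 genes were called. The labels do not say that the arrays came from separate animals, so the p-values measure the spread between these samples, which may be technical.

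The 12 called genes with the largest differences in the AKR direction included genes of the immune system and of epithelia. After Prss22 (3.81 ± 0.12, SE, adjusted p = 6.96e-07, limma), the largest differences were those of BC018473 (2.72 ± 0.15) and Hnrnpl (2.61 ± 0.08), which encodes an RNA-binding regulator of splicing. The other Hnrnpl probe set differed by 0.12 ± 0.11 and was not called. The rest of the 12 genes had no other tested probe set. Gbp8, a guanylate-binding protein gene of the interferon-inducible family, was 3.25-fold higher (1.70 ± 0.09, adjusted p = 1.12e-05, limma). Cldn4, a tight junction gene of medullary thymic epithelium, was 2.36-fold higher (1.24 ± 0.13, adjusted p = 0.000456, limma). A pair of immunoglobulin variable genes, Igkv6-20 (1.28 ± 0.22) and Ighv14-2 (1.24 ± 0.19), and the haemoglobin gene Hba-a2 (1.28 ± 0.14) were also in this group. Myzap (2.34 ± 0.21), Rpl27a (1.85 ± 0.13), Gm13306 (1.43 ± 0.11) and Tmem121 (1.35 ± 0.15) made up the rest. For BC018473, Myzap, Gm13306 and Hba-a2, all 3 DBA arrays lay below the 40th percentile of their array, as did 2 of 3 for Prss22 and 1 of 3 for Igkv6-20. The sizes of these differences and their order are thus not exact. Without sharing of variance between genes, Igkv6-20 (adjusted p = 0.0801) and Ighv14-2 (0.0638) were not called, and both passed limma in the other 18 settings.

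In the DBA direction, Mlycd, which encodes malonyl-CoA decarboxylase of fatty acid oxidation, was 6.54-fold higher (-2.71 ± 0.09, adjusted p = 6.96e-07, limma). Stab2, a scavenger receptor gene of sinusoidal endothelium, was 5.45-fold higher (-2.45 ± 0.11, adjusted p = 4.09e-06, limma). Slc15a2 differed by -3.53 ± 0.61 (adjusted p = 0.00420, limma), with AKR values of 5.44, 8.15 and 7.78. The Slc15a2 call was lost with robust variance estimation (adjusted p = 0.0569, limma) and without sharing of variance between genes (0.0864), and held in 17 of 19 settings. Its 2 other probe sets were not called (-0.18 and -0.26), and the mean of its probe sets differed by -1.33. Zbtb16 (-2.09 ± 0.12), Rgs13 (-2.08 ± 0.16), Col6a3 (-1.95 ± 0.19), a collagen gene, and Inpp4b (-1.87 ± 0.17), a phosphoinositide phosphatase gene, were further members. The remaining genes were 6330403K07Rik (-2.33 ± 0.12), Syt13 (-2.20 ± 0.11), Ercc6 (-2.18 ± 0.10), H2-Ea (-1.92 ± 0.07) and Zfp626 (-1.84 ± 0.20). For Zbtb16, both other probe sets were called in the same direction, and for Syt13, H2-Ea and Inpp4b the 1 other tested probe set was. Mlycd, Stab2, 6330403K07Rik, Ercc6, Rgs13, Col6a3 and Zfp626 had no other tested probe set. For 6330403K07Rik, Ercc6 and Rgs13, all 3 AKR arrays lay below the 40th percentile of their array, as did 2 of 3 for Zfp626. The sizes of the differences of these genes and their order are thus not exact.

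**Figure D1:**
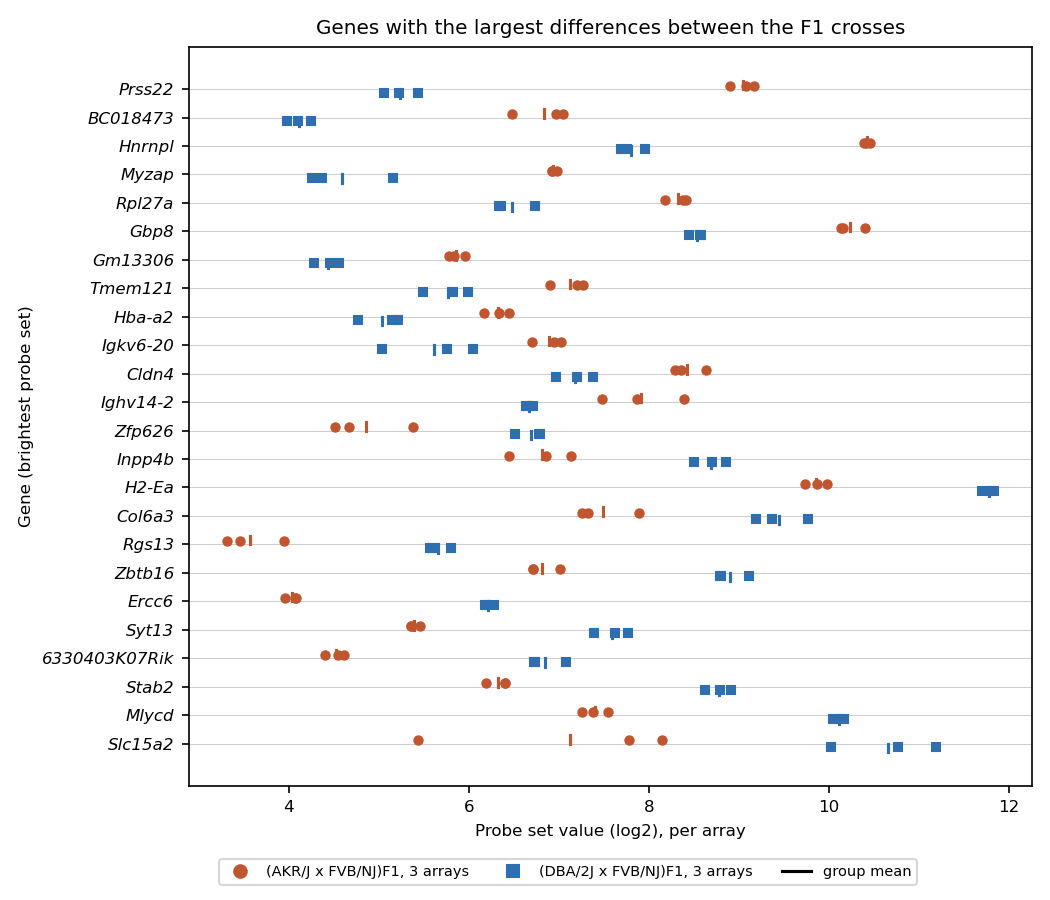
Probe set values on the log2 scale (horizontal axis) for the 12 genes with the largest called difference in each direction (vertical axis), with a circle for each of 3 AKR cross arrays, a square for each of 3 DBA cross arrays and a short line at each group mean. The circles and squares of each gene do not overlap, and the AKR arrays of Slc15a2 spread from 5.44 to 8.15.

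Proliferation genes were shifted towards the AKR cross. Of 24 measured genes, 11 were higher in the AKR cross, 0 were higher in the DBA cross and 13 did not pass, and 14 were higher when adjusted over the list alone. Plk1, a mitotic kinase gene, differed by 0.55 ± 0.10 (1.47-fold), Ccna2, a cyclin gene of S phase and mitosis, by 0.41 ± 0.07, and Rrm2, a subunit of ribonucleotide reductase, by 0.29 ± 0.05. The other Ccna2 probe set differed by 0.10 and was not called. The list median was 0.22, and camera in limma gave an adjusted p = 0.00112 with a preset correlation and an adjusted p = 0.947 with an estimated correlation. Mitochondrial respiratory chain genes had a median of 0.09. Of 25 measured, 6 were higher in the AKR cross and 0 in the DBA cross, also when adjusted over the list alone. Uqcrc1 (0.46 ± 0.08), of complex III, and Atp5b (0.38 ± 0.05), of ATP synthase, were among them. Camera in limma gave an adjusted p = 0.0397 for this list, and an adjusted p = 0.947 with an estimated correlation. The respiratory chain call was lost without AKR replicate 1 (adjusted p = 0.129, limma), AKR replicate 2 (0.0594), DBA replicate 2 (0.131) or DBA replicate 3 (0.0812), and after quantile normalization (0.0615).

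B cell and germinal centre markers were also shifted towards the AKR cross. Of 15 measured, 6 were higher in the AKR cross, 1 was higher in the DBA cross and 8 did not pass, and adjusted over the list alone the counts were 7 and 1. Cr2, complement receptor 2, was higher in the AKR cross (0.93 ± 0.11), with 2 of 3 DBA arrays below the 40th percentile of their array. Cd79a, part of the B cell receptor, was 1.67-fold higher in the AKR cross (0.74 ± 0.10), and Cd22 was 1.43-fold higher (0.52 ± 0.09). Camera in limma gave an adjusted p = 0.0119 for the list, and an adjusted p = 0.743 with an estimated correlation. With the filter at the 60th percentile the list no longer passed (adjusted p = 0.0728, limma). Glycam1, a gene of the high endothelial venules of lymph nodes, stood at 7.83, 7.69 and 7.84 on the AKR arrays and at 8.40, 4.74 and 4.76 on the DBA arrays, and was not called (adjusted p = 0.131, limma). Glycam1 lies outside the lists and was looked up after the B cell values were seen. Of 9 listed immunoglobulin and plasma cell genes, 0 were higher in the AKR cross and 1 was higher in the DBA cross, the same counts as when adjusted over the list alone. This list does not hold Igkv6-20 (1.28) and Ighv14-2 (1.24), which were called higher in the AKR cross.

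Interferon-stimulated genes were shifted towards the DBA cross. Of 25 measured, 10 were higher in the DBA cross, 1 was higher in the AKR cross and 14 did not pass, and adjusted over the list alone the counts were 11 and 1. Oasl2, an oligoadenylate synthetase-like gene, was 1.95-fold higher in the DBA cross (-0.96 ± 0.09), and the GTPase genes Iigp1 (-0.57 ± 0.12) and Irgm1 (-0.43 ± 0.07) had the same direction. Bst2, which encodes tetherin, was the member higher in the AKR cross (0.54 ± 0.09). The list does not hold Gbp8 (1.70), which was called higher in the AKR cross. The adjusted p was 0.00728 by camera in limma, and an adjusted p = 0.947 with an estimated correlation. Granulocyte and mast cell markers had 4 of 12 members higher in the DBA cross and 0 higher in the AKR cross, also when adjusted over the list alone. S100a8, an abundant calcium-binding protein gene of neutrophils, was 1.95-fold higher in the DBA cross (-0.96 ± 0.19). By camera in limma the granulocyte list had an adjusted p = 0.0397, and an adjusted p = 0.947 with an estimated correlation. This call was lost without AKR replicate 1 (adjusted p = 0.109, limma) or DBA replicate 2 (0.106), and with the mean of each gene's probe sets (0.0624).

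Innate-like and gamma-delta T cell markers were higher in the DBA cross for 5 of 11 measured genes, with 0 higher in the AKR cross and 6 not passing, and adjusted over the list alone the counts were the same. Besides Zbtb16, these were Maf (-1.17 ± 0.10), a transcription factor gene, Icos (-0.87 ± 0.09), a costimulatory receptor gene, Id2 (-0.68 ± 0.09), an inhibitor of E proteins, and Cxcr6 (-0.40), a chemokine receptor gene named here after its value was seen. The 2 other probe sets of Id2 were not called (-0.11 and 0.04). Of the 4 other tested probe sets of Maf, 2 were called in the same direction, and for Icos both others were. Camera in limma gave the innate-like list an adjusted p = 0.0119, and an adjusted p = 0.743 with an estimated correlation. Mature single-positive thymocyte markers went both ways, with 5 of 19 higher in the DBA cross and 2 higher in the AKR cross, also when adjusted over the list alone. The median of this list was 0.01 and its mean was -0.14, so they differed in sign. Slfn1, a Schlafen gene of T cells, was 2.58-fold higher in the DBA cross (-1.36 ± 0.12), and Ms4a4b was 1.63-fold higher (-0.71 ± 0.10). Of 13 double-positive thymocyte markers, 1 was higher in each cross, and Cd3e, a chain of the T cell receptor complex, was the one higher in the AKR cross (0.30 ± 0.04). Among 16 early thymocyte markers, 3 were higher in the AKR cross and 0 in the DBA cross. Lyl1, a transcription factor gene of early progenitors, was one of them (0.41 ± 0.10), and its call was lost without AKR replicate 2 (adjusted p = 0.0523, limma) or DBA replicate 3 (0.0531). The double-positive and early lists gave the same counts when adjusted over the list alone. The regulatory T cell list had 1 of 10 members higher in the DBA cross, Nrp1 (-0.40 ± 0.09), and the T cell receptor signalling list had 4 of 17 higher in each cross, both also when adjusted over the list alone. The 3 other tested probe sets of Nrp1 were not called. Lat, a signalling adaptor gene, was higher in the AKR cross (0.28 ± 0.06) and Prkcq, a protein kinase C gene, was higher in the DBA cross (-0.34 ± 0.07).

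Medullary thymic epithelial markers were shifted towards the DBA cross. Of 13 measured medullary markers, 7 were higher in the DBA cross, 1 was higher in the AKR cross and 5 did not pass, and adjusted over the list alone the counts were the same. Csn2, a casein gene expressed ectopically in the medulla, was 1.81-fold higher in the DBA cross (-0.85 ± 0.08), Avil, a gene of tuft-like cells, was 1.80-fold higher (-0.85 ± 0.11), and Epcam, an epithelial adhesion gene, was also higher (-0.59 ± 0.09). The other Epcam probe set differed by 0.15 and was not called. Cldn4 was the medullary marker that went the other way. By camera in limma the medullary list had an adjusted p = 0.0240, and an adjusted p = 0.743 with an estimated correlation. Without DBA replicate 2 the medullary list no longer passed (adjusted p = 0.0527, limma). Of 12 cortical markers, 3 were higher in the AKR cross and 0 in the DBA cross, and adjusted over the list alone the counts were 3 and 1. Foxn1, the master transcription factor gene of thymic epithelium, was 1.59-fold higher in the AKR cross (0.67 ± 0.12), and Ctsl, the cathepsin L gene, was 1.24-fold higher (0.31 ± 0.04). The other Foxn1 probe set differed by 0.33 and was not called. The cortical list did not pass camera (adjusted p = 0.901, limma), and its median (-0.01) and mean (0.07) differed in sign. No test of the difference between the cortical and medullary lists was run.

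**Figure D2:**
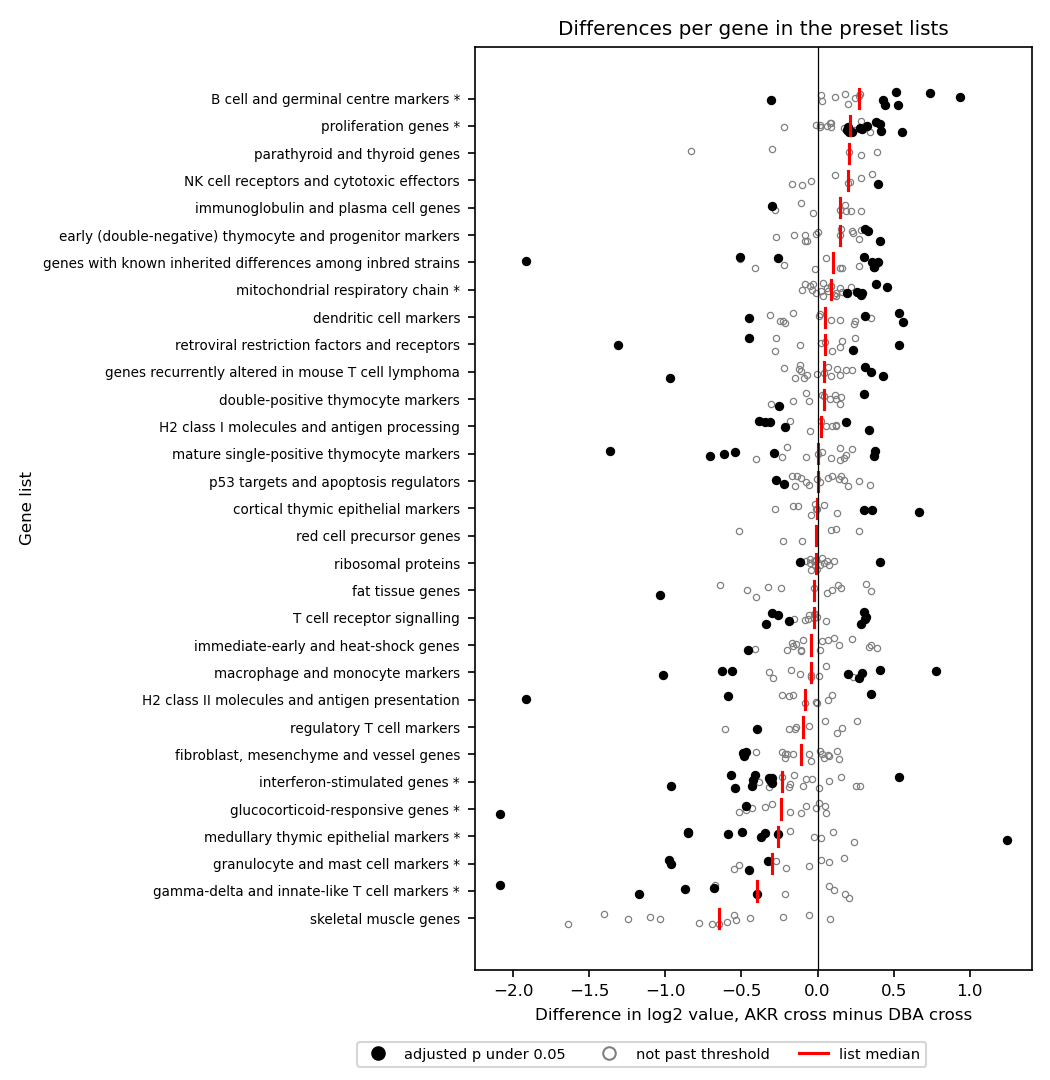
Difference in log2 value, AKR cross minus DBA cross (horizontal axis), for each measured gene of the 31 gene lists (vertical axis), with filled points for genes with an adjusted p under 0.05, open points for the others, a red line at each list median and an asterisk at the 8 lists that passed camera with a preset correlation. The B cell list has a median of 0.27 and the innate-like T cell list a median of -0.40, and the single genes of most lists lie on both sides of 0.

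Genes of the major histocompatibility complex, named H2 in the mouse, differed both between genes and between probe sets of 1 gene. Of 11 class II genes, 2 were higher in the DBA cross and 1 in the AKR cross, and adjusted over the list alone the counts were 3 and 1. H2-Ea differed by -1.92 ± 0.07 on its brightest probe set (adjusted p = 1.43e-06, limma) and by -3.96 ± 0.09 on another, while H2-DMb2 differed by -0.59 ± 0.08 and H2-Oa by 0.35 ± 0.07. Without AKR replicate 3 the class II list passed camera (adjusted p = 0.0447, limma), and with all arrays it did not (0.151). Of 13 class I and antigen processing genes, 4 were higher in the DBA cross and 2 in the AKR cross, also when adjusted over the list alone. H2-K1 (-0.31 ± 0.04) and Psmb9 (0.34 ± 0.05), an immunoproteasome subunit gene, went opposite ways. The class I list had a median of 0.02 and a mean of -0.04, which differed in sign. The 8 tested probe sets of H2-D1 disagreed. The brightest of them differed by -0.21 ± 0.04. Another read 16.4-fold higher in the DBA cross (-4.03 ± 0.09), and a further one read 26.5-fold higher in the AKR cross (4.73 ± 0.10). Probe sets of 1 gene that move so far in opposite directions do not measure its RNA level. These folds are thus no size or direction of a difference in H2-D1 expression. Sequence variants under these probes stay open and were not checked.

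**Figure D3:**
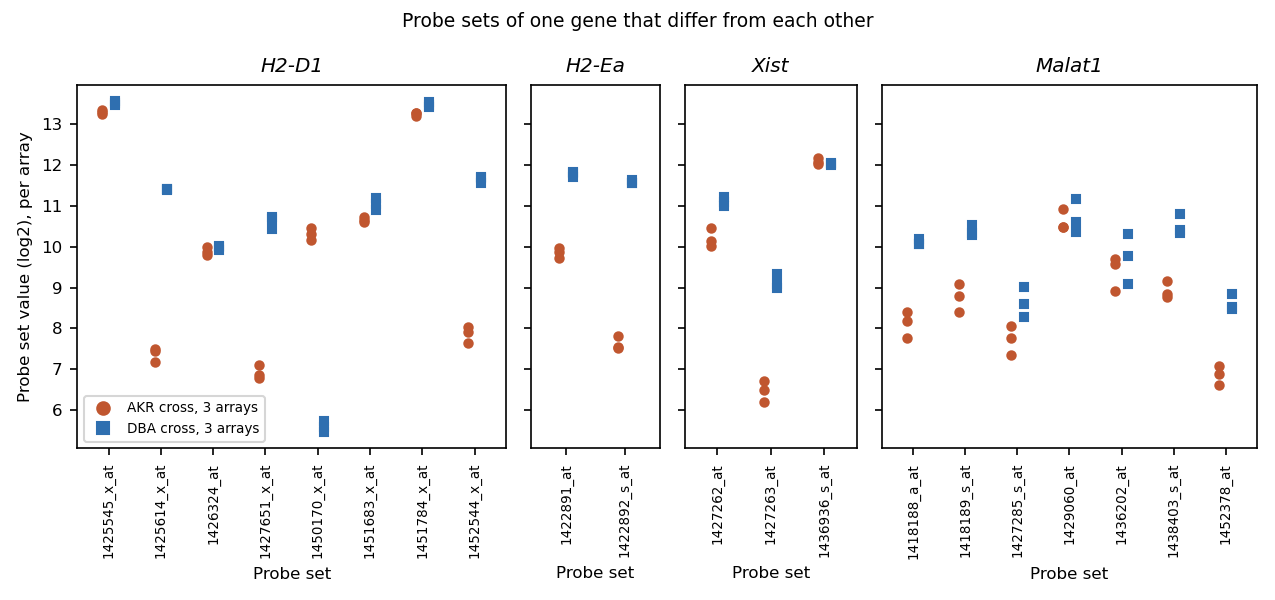
Log2 values (vertical axis) of each tested probe set (horizontal axis) of H2-D1, H2-Ea, Xist and Malat1, with a circle for each of 3 AKR cross arrays and a square for each of 3 DBA cross arrays. H2-D1 has probe sets that are far higher in either cross. The brightest probe set of Xist has group means of 12.10 and 12.03, while its 2 others are both lower in the AKR cross, 1 of them by -2.67.

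Genes known to vary between inbred strains went both ways. Thy1, a thymocyte surface antigen, differed by 0.37 ± 0.05 (1.30-fold higher in the AKR cross), and Glo1, the glyoxalase gene, by 0.36 ± 0.06. Klrd1, the CD94 receptor gene, differed by 0.40 ± 0.09, and its call was lost without AKR replicate 2 (adjusted p = 0.0505, limma). Gpnmb (0.06 ± 0.09) and Fv1 (0.16 ± 0.11), a retroviral restriction gene, were not called. Of 16 such genes, 5 were higher in the AKR cross and 3 in the DBA cross, and adjusted over the list alone the counts were 6 and 5. Of 13 retroviral restriction factors and receptors, 2 were higher in each cross, also when adjusted over the list alone. Trim30a, a regulator of innate signalling, was 2.48-fold higher in the DBA cross (-1.31 ± 0.07), and Xpr1, a retrovirus receptor gene, was 1.37-fold higher (-0.45 ± 0.08). Of 19 genes recurrently altered in mouse T cell lymphoma, 3 were higher in the AKR cross and 1 in the DBA cross, and adjusted over the list alone the counts were 4 and 1. Evi5, named for a viral integration site, was 1.96-fold higher in the DBA cross (-0.97 ± 0.11), and Ccnd3, a D-type cyclin gene, was 1.35-fold higher in the AKR cross on its brightest probe set (0.43 ± 0.08), with 1 other probe set called in the same direction and 1 in the opposite direction. The other Evi5 probe set differed by -0.24 and was not called. The strain and retroviral lists had medians of 0.10 and 0.05 and means of -0.09 and -0.07, so these differed in sign. Xist, the noncoding RNA of the inactive X chromosome, was bright in both crosses (12.10 and 12.03), and all 6 arrays carry a female label. Its brightest probe set was not called, while its 2 others were both called lower in the AKR cross, 1 of them by -2.67 ± 0.14.

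Macrophage and dendritic cell markers held differences in both directions. Of 17 macrophage and monocyte markers, 5 were higher in the AKR cross and 3 in the DBA cross, and adjusted over the list alone the counts were 6 and 5. Cd163 (-1.02 ± 0.18) and Mrc1 (-0.63 ± 0.08), scavenger and mannose receptor genes of tissue macrophages, were higher in the DBA cross, with 1 of 3 AKR arrays of Cd163 below the 40th percentile, and Timd4, a phosphatidylserine receptor gene, was 1.72-fold higher in the AKR cross (0.78 ± 0.15). Of 16 dendritic cell markers, 3 were higher in the AKR cross and 1 in the DBA cross, and adjusted over the list alone the counts were 4 and 1. Cd209a, a lectin gene, was higher in the AKR cross (0.56 ± 0.11), and Fscn1 was higher in the DBA cross on its brightest probe set (-0.45 ± 0.10) and higher in the AKR cross on 2 of its 3 others (0.82 and 0.42), with none of the others called in the DBA direction. Of 9 natural killer cell genes, Klrd1 alone was called, also when adjusted over the list alone. Of 18 fibroblast, mesenchyme and vessel genes, 3 were higher in the DBA cross, also when adjusted over the list alone, among them Postn (-0.49 ± 0.08) and Mgp (-0.47 ± 0.08), genes of the extracellular matrix. The stromal list did not pass camera with all arrays (adjusted p = 0.0781, limma), and passed without AKR replicate 2 (0.0167) or DBA replicate 3 (0.00924), and with no filter on dim probe sets (0.0251).

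Among markers of tissue that can be dissected with the thymus, the muscle list stood apart on 1 array. The median of 15 skeletal muscle genes was 9.79 on DBA replicate 1 and between 5.99 and 7.39 on the other 5 arrays. The median of 13 fat tissue genes was 9.99 on DBA replicate 1 and between 7.75 and 9.40 on the others, with spread within both crosses. None of the 15 muscle genes was called by limma, with a list median of -0.65, and without DBA replicate 2 the muscle list passed camera (adjusted p = 0.00652, limma). Of the fat genes, 1 was higher in the DBA cross and 12 did not pass, and adjusted over the list alone 0 passed. None of 5 parathyroid and thyroid genes and none of 6 listed red cell precursor genes was called, also when adjusted over the list alone. The haemoglobin gene Hba-a2 (1.28), called higher in the AKR cross, is not among these 6. The parathyroid and thyroid list had a median of 0.21 and a mean of -0.05, which differed in sign.

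Few stress and housekeeping genes were called. Glucocorticoid-responsive genes had 2 of 14 members higher in the DBA cross, Zbtb16 and Per1, and 0 higher in the AKR cross, also when adjusted over the list alone. Zbtb16 also belongs to the innate-like list. Camera in limma gave the glucocorticoid list an adjusted p = 0.0397, and an adjusted p = 0.947 with an estimated correlation. Its call was lost without AKR replicate 1 (adjusted p = 0.228, limma), DBA replicate 2 (0.106) or DBA replicate 3 (0.223), with the filter at the 60th percentile (0.0728), after cyclic loess (0.0642), with the mean of probe sets (0.205) and with fry (0.243). The Per1 call (-0.47 ± 0.13) was lost without AKR replicate 1 (adjusted p = 0.0946, limma), AKR replicate 2 (0.0771), DBA replicate 2 (0.0857) or DBA replicate 3 (0.0967). Of 18 immediate-early and heat-shock genes, 1 was called, also when adjusted over the list alone, Jun, a transcription factor gene (-0.46 ± 0.09). The other Jun probe set differed by -0.33 and was not called. Of 18 p53 targets and apoptosis regulators, 2 were higher in the DBA cross, and 0 passed when adjusted over the list alone. The apoptosis list had a median of 0.00 and a mean of 0.02, while camera gave the opposite sign. Of 17 listed ribosomal protein genes, 1 was higher in each cross, also when adjusted over the list alone, and Rps6 was the one higher in the AKR cross (0.41 ± 0.07). Rpl27a (1.85), called higher in the AKR cross, is not among these 17. The ribosomal list had a median of -0.01 and a mean of 0.02, which differed in sign.

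Across the 31 lists, camera in limma with a preset correlation called 8, with 3 shifted towards the AKR cross and 5 towards the DBA cross. It called 5 lists without AKR replicate 1, without DBA replicate 2 or with the mean of probe sets. With an estimated correlation it called 0 lists, with 1 list at an unadjusted p under 0.05 and a lowest adjusted p of 0.743. The fry test in limma, which asks whether the genes of a list move on balance one way, called 3 lists, the B cell, innate-like and medullary lists (adjusted p = 0.0208 each).

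Of the probe sets without a single gene symbol, 4314 were tested and 1258 were called. At least 2-fold differences leaned to the DBA cross here as well, with 35 probe sets higher in the AKR cross and 227 higher in the DBA cross. Among called probe sets that have no symbol and whose groups did not overlap, the largest differences in the AKR direction were 4.58 ± 0.26 and 2.87 ± 0.15. In the DBA direction they were -5.31 ± 0.24 and -4.64 ± 0.65. The means of the lower group were 3.82, 4.08, 3.63 and 5.27 in this order, against 40th percentiles of 5.21 to 5.28 on the arrays. The lower group was thus dim, and these differences and their order are not exact.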

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

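The tests of the control probe sets were chosen only after the result was seen. Control probe sets on the array, which take no part in the gene comparison, differed between the crosses. The 24 probe sets of Bacillus poly-A controls, which match no mouse gene, were all higher in the AKR cross, with a median difference of 0.50 and no overlap for 22 of them. An exact permutation test of the array medians gave p = 0.1 (two-sided), the smallest that 3 arrays against 3 can give. The 18 hybridization controls went the other way, with 0 higher in the AKR cross and a median difference of -0.58, with no overlap for 2 of them (exact permutation test, two-sided, p = 0.3). The probe set for the 5 prime end of 18S ribosomal RNA differed by -1.24, at 5.48 ± 0.06 in the AKR cross against 6.72 ± 0.72 in the DBA cross (mean ± SD, n = 3 each). The probe set for the B1 repeat differed by -0.63, at 11.65 ± 0.24 against 12.28 ± 0.04 (mean ± SD, n = 3 each). These were the largest differences of 3 probe sets each, and the 3 prime probe set of 18S ribosomal RNA (-0.21) and a probe set of the B2 repeat (-0.02) overlapped between the crosses. These signals stand here because they lie in data outside the gene comparison.

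The 3084 called genes may in part reflect arrays of the 2 crosses that were prepared or hybridized apart from each other, since the poly-A controls differ by 0.50 with the cross. This cannot be told apart from the cross, because such batches would each hold 1 cross and the labels name none. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called probe sets (7449) and 1 as many called genes (3084), the real one in both cases, and the highest other split gave 0, but 10 splits are too few for a share under 0.05. For called genes with another tested probe set, sequence variants under single probe sets are argued against as the whole cause. The next brightest probe set of these genes had the same direction in 79.6% of 1660 genes (exact 95% interval 77.6% to 81.6%). For genes not called the share was 64.7%, which also passed the bound set in advance, so passing it alone decides nothing. Of the next brightest probe sets of called genes, 624 were themselves called in the same direction and 63 in the opposite one. Called genes with 1 tested probe set, among them Prss22, Mlycd and Stab2, are not reached by this. Variants under several probe sets of 1 gene could also give the same direction, and were not tested. The difference in genotype that the design names stays open and untested.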

How the results depend on the processing

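The alternative without probe sets that can match several transcripts was chosen after seeing the data. All 3084 called genes kept their sign under the normalizations and each left-out array. Genes selected for a difference large against its spread can hardly turn when 1 array is left out. The variance models and the t-test use the same differences, so signs cannot change under them. The sign was kept by 2999 of 3084 genes under the mean of a gene's probe sets and by 2977 of 3011 without the shared probe sets. Of 109 genes taken by the naming rule, 41 lost the call under the t-test. With 1 array left out, from 10 (without AKR replicate 3) to 17 (without DBA replicate 2) lost it. A t-test with equal variance called 3544 probe sets (1595 higher in the AKR cross, 1949 in the DBA cross) and 1367 genes (726 and 641), without shared variance estimates. With the mean of a gene's probe sets, 18 genes were at least 2-fold higher in the AKR cross and 5 lists passed; with an estimated correlation 0 lists passed and with fry 3. The cause of other changes was not tested. With 1 array left out, called probe sets ran from 5161 to 6317 (higher in AKR 2158 to 2978, in DBA 2881 to 3706), genes from 1843 to 2519 (893 to 1422 and 948 to 1200), 2-fold genes from 26 to 36 and from 87 to 107, and lists from 5 to 9, with fewer arrays in each fit. Whether the numbers 1 to 3 pair the arrays stays undecided, and the main fit used no pairing. Deviation correlations of same-numbered arrays were 0.389, 0.0697 and 0.371. For each AKR array the same-numbered DBA array was the closest, while DBA replicate 2 was closest to AKR replicate 3 at 0.0748. The replicate block gave 4194 called genes, 3081 of them shared with the fit without a block. No log offset was run, since the values were already log2.

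Adjusted list p-values without 1 array ran from 0.00260 to 0.0190 (innate-like), 0.00775 to 0.0527 (medullary), 0.00540 to 0.0262 (B cell), 0.0124 to 0.109 (granulocyte), 7.18e-06 to 0.0125 (proliferation), 0.000538 to 0.0190 (interferon), 0.000249 to 0.228 (glucocorticoid) and 0.00497 to 0.131 (respiratory chain). With an estimated correlation they were 0.743 for the innate-like, medullary and B cell lists and 0.947 for the other 5. The filter at the 60th percentile gave 0.0728 for the B cell and glucocorticoid lists. The mean of probe sets gave 0.0624 (granulocyte), 0.205 (glucocorticoid) and 0.243 (respiratory chain), cyclic loess 0.0642 (glucocorticoid), quantile normalization 0.0615 (respiratory chain), and the fit without shared probe sets 0.0901 (granulocyte). With fry they were 0.236 (granulocyte), 0.0998 (proliferation), 0.0829 (interferon) and 0.243 (glucocorticoid and respiratory chain). Direction turned for Fscn1 (0.22), Tox (-0.16) and Xist (-1.16) under the mean of probe sets and for Xist (-0.89) without the shared probe sets, because their probe sets disagree.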

Other observations

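The tests of dim probe sets, of degradation and of transcript parts, and the look at the other probe sets of nuclear RNAs, were chosen only after the result was seen. The test of dim probe sets replaced one written earlier, which compared probe sets with and without a gene symbol and says nothing of direction. Tested genes that follow each other on the genome (assembly GRCm38.p6), with untested genes between them left out, and that were called in the same direction formed 35 pairs with both differences of at least 1.5-fold, 29 of them higher in the DBA cross and 6 in the AKR cross. Genes in this paragraph were named after their values were seen. Vars2 (-1.53), Gtf2h4 (-1.57) and Ddr1 (-1.77) are neighbours in this sense, and encode a tRNA synthetase, a transcription and repair factor subunit and a collagen receptor. The Schlafen genes Slfn5 (-0.83), Slfn9 (-0.61) and Slfn8 (-1.27) are a further run, with the other probe set of Slfn5 called in the opposite direction. In the AKR direction, Pomt1 (0.79), Uck1 (0.76) and Swi5 (0.64) are neighbours.

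Neighbouring genes differed in the same direction more often than shuffled gene order gave. Of 12781 neighbouring pairs of tested genes, 589 were both called in 1 direction, against a mean of 368 in 100000 shuffles (maximum 448, permutation p = 1e-05, the smallest they can give). Inherited variants that act on neighbouring genes are a candidate explanation, and 555 pairs whose symbols start differently, against a mean of 351, argue against gene families as the whole cause. For genes of these pairs with another tested probe set, sequence variants under single probe sets are argued against as the whole cause. Their next brightest probe set had the same direction in 82.6% of 530 genes (exact 95% interval 79.1% to 85.8%). For genes not called the share was 64.7%, which also passed the bound set in advance. Of the next brightest probe sets of the paired genes, 231 were themselves called in the same direction and 19 in the opposite one. Paired genes with 1 tested probe set are not reached by this. Variants under several probe sets of 1 gene, or of neighbours, could also give the same direction, and were not tested. Co-regulated neighbours within 1 cell type, or a cell type that differs in share, were not tested.

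Differences of at least 2-fold were mostly higher in the DBA cross, for 618 probe sets against 122. Compression of dim probe sets is argued against as the whole cause, since in the brighter 5 of 10 equal bins of mean value 82.2% of 286 such calls were higher in the DBA cross (exact 95% interval 77.2% to 86.4%), against 84.4% of 454 in the dimmer bins, though the share of probe sets with a symbol that were 2-fold higher in the DBA cross fell from 2.49% in the dimmest bin to 0.517% in the brightest. More nuclear RNA in the DBA libraries is argued against as the whole cause. The 15 noncoding RNAs listed as nuclear had a median of -0.14 on their brightest probe sets (95% bootstrap interval -0.24 to -0.02). All 46 of their probe sets had a median of -0.15 (-0.25 to -0.05). These intervals resample genes or probe sets, not arrays, and so leave out the spread between samples. A small excess stays open, with 12 of 15 negative and 5 of 7 probe sets of Malat1 called higher in the DBA cross (-0.91 to -1.99). More unspliced RNA also stays open, since this list does not measure it in other genes. More degraded RNA in 1 cross cannot be told apart, since the 3 prime minus 5 prime value differed by -0.0413 for Actb and by -0.0194 for Gapdh but by 1.03 for 18S ribosomal RNA. The mRNA controls Actb and Gapdh thus showed no excess of degraded RNA in either cross, and the question stays open through a ribosomal RNA, not an mRNA. Parts of transcripts that the brightest probe set does not read may contribute and cannot be told apart, since dimmer probe sets of a gene held more 2-fold calls in the DBA direction (odds ratio 3.65, 95% interval 2.59 to 5.13) and in the AKR direction (2.52), with a ratio between directions of 1.39 (Fisher's exact test, p = 0.344).

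The higher values of Zbtb16, Maf, Icos, Id2 and Cxcr6 in the DBA cross may reflect more NKT and innate-like T cells, as a hypothesis. For Id2 this rests on its brightest probe set, since its 2 others were not called. A separate list of 16 measured NKT cell genes, none of them in the innate-like list, had a median difference of -0.22, with 15 of 16 negative. The 95% bootstrap interval over genes, not arrays, was -0.32 to -0.07. Il4 (-1.21, not an exact size, since all 3 AKR arrays lay below the 40th percentile) and Il18r1 (-0.74) were higher in the DBA cross, and Gata3 (0.46) was higher in the AKR cross, and these 3 were named after their values were seen. The fry test in limma passed its threshold, but the median missed the size of 0.3 set for the hypothesis in advance, so the test stays undecided. Higher levels of these genes per cell remain open.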
